A study of Mus musculus with 8 samples.

How the data were processed

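Total RNA of mouse tibialis anterior muscles was measured on Illumina MouseRef-8 bead arrays, 1 array for each of 8 muscles. Per the labels' protocols, muscle RNA was extracted with TRIzol, purified with an RNeasy kit and DNase, amplified and labelled with biotin. The values analysed are those the authors deposited, on a log2 scale. The scale follows from the values, which ran from 8.10 to 15.29, with a median of 8.33. At any 1 rank the arrays differed by at most 0.155 and typically by 0.0046, so the deposited log2 values had been normalized between arrays by the authors before deposit. The method, the treatment of background, detection p-values and software are not given in the sources used here. The floor near 8.10 means that background was kept or the low end compressed, and a fold change of a dim gene is smaller on this scale than the change of its mRNA. For arrays, no depth is stated, and the number of arrays limits the precision.

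Samples were grouped by their titles into 4 control and 4 spermine oxidase muscles, the only comparison the labels give. The titles number the muscles 1 to 4 in both groups, and the protocol speaks of muscles on both sides, but no label says that equal numbers mark the same mouse, so no replicate block was used. Probes were named through GEO's platform annotation: 23978 of 25697 probes had 1 gene, 0 had several and 1719 were unnamed here. Entrez identifiers of 23962 named probes were found in the RefSeq gene table (assembly GRCm38.p6), 16 were not, and 0 symbols needed an update. Each of the 16593 genes was represented by the probe with the highest mean over all 8 arrays, and 4777 genes had more than 1 probe. Where the probes of a gene named in the text disagree, the text says so for the main cases. Dimmer probes of Asns, Camk2a, Cd163, Cdk1, Cdkn1a, Dnaic1, Dnajb9, Eif2s2, Fmod, Kcnc4, Me1, Ms4a7, Ncam1, Pecam1 and Phka1 differed by less than the brightest, and those of Dnajb9 and 1 of Cdk1, at the floor, had the other sign. No filter on dim probes was applied. No genome positions are given because the array values carry none.

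Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every p-value in the text given for a gene comes from this fit unless an exact test or another setting is named. Smox, the gene on the plasmid, was also tested by an exact two-sided permutation test over the 70 labelled splits of 4 against 4, whose smallest p is 0.0286. Gene lists for muscle, polyamine oxidation, stress, atrophy and the other cell types a muscle can hold, 30 in all with 791 entries, were fixed before the data were examined, and 87 entries were not measured. Some genes stand in more than 1 list, such as Myh8, Cdkn1a and Gadd45a, and the lists are therefore not independent. They were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 30 lists. List scores were compared by the same exact permutation test. Array weights used statmod 1.5.0, and the plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

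The rule for naming genes was fixed before the data were examined. It takes Smox; the 12 genes with the largest rise and the 12 with the largest fall among those past an adjusted p of 0.05 without overlap of the groups or, where fewer than 12 pass, those that pass and then the genes with the smallest unadjusted p, up to 6 in each direction; and up to 4 genes with the smallest p from each list. Clone and predicted genes were named only among the first 5. The genes with at least 2-fold differences, and list members beyond the first 4 that passed over the list alone, were added after their values were seen.

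The fit was tested on simulated data for the spermine oxidase against control comparison, with 16593 genes and the real spread, in 5 draws of 200 changed genes. It recovered 72.8% of genes changed by 0.5 log2 units, 97.3% of those changed by 1 and 99.7% of those changed by 2, with 4.26% of calls wrong. The changed genes were drawn at random from those with a mean signal above the median, and genes were independent. These rates need not hold for the real data, where no gene with an at least 2-fold difference passed the unpaired fit. Camera called 20 of 20 shifted and 0 of 20 unshifted simulated lists, in genes simulated without correlation. Alternatives tried were the replicate block, quantile, median and loess normalization of the deposited values, filters on the dimmest 40% and 60% of probes, the mean of a gene's probes, every probe on its own, an intensity trend with a robust prior, array weights, an unmoderated test per gene, an offset of 16 on the linear scale, other thresholds and leaving out each muscle. Leaving out control replicate 4 and spermine oxidase replicate 1 together was added after seeing the data. Where these muscles lie furthest apart in their groups, leaving both out must shrink the difference.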

Results

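Gene expression was measured in the tibialis anterior, a hindlimb muscle made mostly of fast fibres, of male C57BL/6 mice (a common inbred laboratory strain) aged 8 weeks. The muscles had been transfected 7 days earlier with a plasmid encoding spermine oxidase or with a control plasmid, and the series asks how raising spermine oxidase changes muscle mRNA. Spermine oxidase, the product of Smox, turns spermine into spermidine and releases hydrogen peroxide and an aldehyde. There were 4 muscles in each group, each on 1 Illumina bead array of 25697 probes. The labels do not say whether the muscles came from separate animals, so p-values measure the spread between these samples, which may be partly technical. All values are log2 signals, differences are spermine oxidase minus control, and errors of differences are standard errors from limma. The median signal was 8.33 on every array, single values ran from 8.10 to 15.29, and arrays correlated with one another at 0.975 to 0.997 across probes. The signal has a floor near 8.10, so fold changes of dim genes are understated, and the number of arrays limits the precision.

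Smox was higher in each of the 4 muscles given the spermine oxidase plasmid than in any of the 4 control muscles, on each of its 5 probes. The brightest probe, ILMN_1247267, read 10.78 ± 0.43 (SD, n = 4) in control muscles and 11.94 ± 0.47 (SD, n = 4) in spermine oxidase muscles, which is 2.23-fold. Its log2 difference was 1.16 ± 0.28, and the next probe, ILMN_2597030, gave 1.15 ± 0.29. The other 3 probes lay close to the floor in control muscles and differed more. ILMN_2608052 read 8.83 ± 0.23 in control muscles and 12.27 ± 0.77 after the spermine oxidase plasmid, a 10.8-fold difference. ILMN_2766469 differed by 10.1-fold and ILMN_1256359 by 9.87-fold. For each of the 5 probes the exact two-sided permutation test over the 70 labelled splits gave p = 0.0286, the smallest it can give here. With limma over all genes the brightest Smox probe had an adjusted p = 0.233 and ranked 265 of the 16593 genes. That rank is for the brightest probe, which stands for Smox in this fit. The 3 probes close to the floor differed by 3.44 ± 0.35, 3.34 ± 0.35 and 3.30 ± 0.38. With limma over all probes, each of these 3 had an adjusted p = 0.139. In the same limma fit the brightest probe had an adjusted p = 0.248 and ILMN_2597030 an adjusted p = 0.265. Leaving out control replicate 4 and spermine oxidase replicate 1 together, a choice made after seeing the data, lowered the brightest probe's log2 difference to 0.74.

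**Figure D1:**
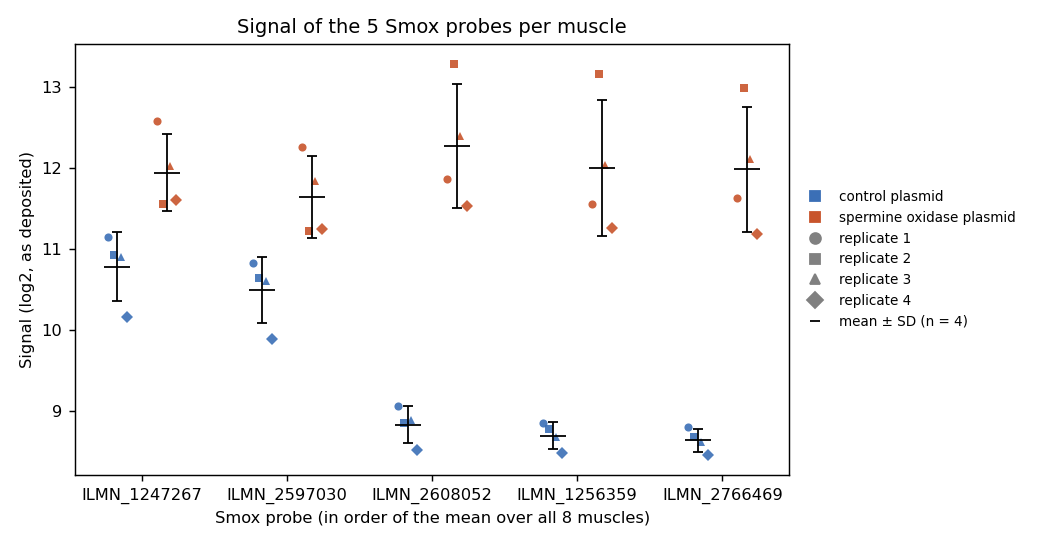
Signal of the 5 Smox probes (horizontal axis, probe identifiers) on the deposited log2 scale (vertical axis) in each of the 8 muscles; colours give the plasmid, symbols the replicate number, and bars the mean ± SD of 4 muscles. All 4 spermine oxidase muscles lie above all 4 control muscles on each probe, with control means of 10.78 and 10.49 on the first probes and 8.83, 8.70 and 8.64 on the others.

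The genes with the smallest p-values among those higher after spermine oxidase were Pik3ip1, an inhibitor of phosphoinositide 3-kinase (log2 difference 0.31 ± 0.03), Stau2, a double-stranded RNA-binding protein (0.31 ± 0.04), Eif2s2, the beta subunit of translation initiation factor eIF2 (0.59 ± 0.07), Dcun1d5 (0.19 ± 0.02), 4833439L19Rik (0.44 ± 0.06) and Pcolce2, an enhancer of procollagen processing (0.35 ± 0.05). Among those lower they were Cdsn (-0.24 ± 0.03), Hint2, a mitochondrial nucleotide hydrolase (-0.26 ± 0.03), Dnaic1 (-0.35 ± 0.04), Dync1i2, a dynein intermediate chain (-0.23 ± 0.03), Srpk3, a muscle protein kinase that acts on splicing factors (-0.54 ± 0.08), and Scarb2, a lysosomal membrane protein (-0.35 ± 0.05). Each of these 12 genes separated the groups without overlap, and each missed the threshold in the unpaired fit, with limma adjusted p-values of 0.147 to 0.179. Pik3ip1, Pcolce2, Cdsn and Dnaic1 lay near the floor, with control means of 8.74, 8.57, 8.53 and 8.92. A second Cdsn probe, at the floor, differed by 0.0048 ± 0.03. In all, 0 of 16593 genes passed an adjusted p of 0.05 with limma in the unpaired fit, 1833 had an unadjusted p under 0.05 (1050 higher, 783 lower) and chance would give 830 on average. That average hides a wide spread, since another split of the 8 muscles into 4 and 4 gave 1779. Other variance models of the unpaired fit gave 8 genes (limma with an intensity trend and robust prior) or 0 (an unmoderated test per gene), and leaving out spermine oxidase replicate 2 gave 13. With the replicate number as a block in limma, 266 genes passed, but no label says that equal numbers pair the muscles. The groups did not overlap for 1025 genes, or 6.18%, where chance gives 2.86%.

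The genes that differed by at least 2-fold, named here after their values were seen, were few: 6 higher and 5 lower. None of them passed the adjusted threshold in the unpaired limma fit. Mmp13, the collagenase matrix metalloproteinase 13, was 5.23-fold lower, at 12.17 ± 0.40 in control muscles and 9.78 ± 0.90 after spermine oxidase (SD, n = 4), with an adjusted p = 0.179. A second Mmp13 probe was lower by a smaller amount (-0.66 ± 0.11), and the third lay at the floor (-0.0041 ± 0.02). The other lower genes were Atp1b4, a muscle protein related to the sodium pump beta subunits (-1.29 ± 0.24), Myh8, the perinatal myosin heavy chain (-1.28 ± 0.38), Maged2 (-1.12 ± 0.27) and Apoe, apolipoprotein E (-1.02 ± 0.34). Besides Smox, the higher genes were Chad, the cartilage matrix protein chondroadherin (1.40 ± 0.28), Dusp26, a protein phosphatase (1.26 ± 0.22), Ppp1r1a, an inhibitor of protein phosphatase 1 (1.09 ± 0.31), Fmod, the collagen-binding proteoglycan fibromodulin (1.06 ± 0.18), and Ces1d, a carboxylesterase (1.02 ± 0.24). Of these 11 genes, Apoe, Ppp1r1a and Ces1d overlapped between the groups.
Of 30 gene lists fixed before the data were examined, 17 were called by camera, which asks whether a list's genes differ more in one direction than other genes, at a preset correlation between genes of 0.01. There were 8 lists higher and 9 lower after spermine oxidase. With the correlation estimated for each list 0 of the 30 were called, and the smallest adjusted p was 0.360. For the 17 called lists the estimates ran from 0.023 to 0.86. The camera p-values at the preset 0.01 therefore assume less correlation than was estimated from these data. Fry, which asks whether a list's genes move one way on balance, called 1, tendon and cartilage. Fry's mixed test, which asks whether a list's genes differ in any direction, called 15. Of the lists not called by camera, it called adipocytes (adjusted p = 0.0045), p53 targets and insulin and IGF signalling (0.0288 for both), aldehyde detoxification (0.0356) and polyamine metabolism (0.0406). A list's score is the mean over its genes of each gene's log2 deviation from its mean over all 8 muscles. Scores separated the groups without overlap for 5 lists (exact permutation p = 0.0286, the smallest possible, and 0.171 adjusted over the 30 lists). For a single list, chance gives that separation in 2.86% of splits. No gene of any list passed when adjusted over all genes in the unpaired fit.

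Genes of immature, slow and denervated fibres were lower after spermine oxidase. Of 20 measured genes of satellite cells, the stem cells of muscle, and of regenerating fibres, 16 were lower, and the score fell by 0.34 (camera adjusted p = 1.18e-05, and adjusted p = 0.456 with an estimated correlation). Myl4, an embryonic myosin light chain, fell by 0.87 ± 0.18 and was the only gene of this list to pass adjusted over the list alone. Myh8 read 14.90 ± 0.17 in control muscles and 13.62 ± 0.84 in spermine oxidase muscles, Igf2, a fetal growth factor, differed by -0.87 ± 0.24, and Itga7, a laminin receptor, by -0.29 ± 0.09, without passing. The second Myh8 probe, at 13.58 in control muscles, differed more, by -1.73 ± 0.42, than the brightest (-1.28 ± 0.38), which lay near the top of the scale. The slow and oxidative fibre list was lower in 12 of 16 genes, with a score difference of -0.32 (adjusted p = 0.000441, and 0.456 as the adjusted p with an estimated correlation). Its genes Tnni1 (-0.86 ± 0.20), Tnnt1 (-0.72 ± 0.21), Casq2 (-0.75 ± 0.20), Atp2a2 (-0.70 ± 0.21) and Myl6b (-0.42 ± 0.12), which encode slow troponins, a calsequestrin, the slow-fibre calcium pump and a myosin light chain, fell when adjusted over the list alone. The denervation and neuromuscular junction list was lower in 17 of 21 genes, with a score difference of -0.27, a median gene at -0.077 and no overlap between groups (adjusted p = 0.00101, and adjusted p = 0.456 with an estimated correlation). None of its genes passed over the list alone. Among them Chrng, the fetal subunit of the acetylcholine receptor, differed by -0.88 ± 0.24, Sln, the calcium pump regulator sarcolipin, by -0.84 ± 0.23 and Ncam1, an adhesion molecule of immature and denervated fibres, by -0.63 ± 0.16. Myh8 belongs to this list too.

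Genes of energy metabolism and of excitation-contraction coupling were higher. All 25 measured genes of glycolysis and glycogen metabolism were higher, with a score difference of 0.17 (adjusted p = 1.63e-06, and adjusted p = 0.456 with an estimated correlation). Fbp2, the muscle fructose bisphosphatase (0.68 ± 0.13), Phka1, a subunit of phosphorylase kinase (0.46 ± 0.09), Pygm, the muscle glycogen phosphorylase (0.34 ± 0.09), and Pfkm, the muscle phosphofructokinase (0.096 ± 0.025), rose when adjusted over the list alone. The dimmer Pfkm probes differed more, by 0.20 ± 0.09 and 0.51 ± 0.14, than the brightest, which lay near the top of the scale at 14.69. Oxidative phosphorylation was higher in 43 of 52 genes by 0.086 on average (adjusted p = 1.18e-05, and adjusted p = 0.456 with an estimated correlation), led by the complex I subunit Ndufb5 (0.50 ± 0.10) and the ATP synthase subunit Atp5h (0.15 ± 0.04), which did not pass over the list alone. The list of the tricarboxylic acid cycle and fatty acid oxidation was higher in 29 of 36 genes by 0.12 (adjusted p = 0.000363, and adjusted p = 0.456 with an estimated correlation), and Decr1, a dienoyl-CoA reductase of fatty acid oxidation, rose by 0.31 ± 0.06 over the list alone. Without spermine oxidase replicate 1, these last differences were 0.052 and 0.072. The excitation-contraction list was higher in 15 of 19 genes by 0.14 (adjusted p = 0.00214, and adjusted p = 0.456 with an estimated correlation) and by 0.087 without control replicate 4. The potassium channel gene Kcnc4 (0.91 ± 0.21), the calmodulin gene Calm3 (0.26 ± 0.04) and the kinase gene Camk2a (0.33 ± 0.10) rose over the list alone, and Sypl2, which encodes a protein of the triad membrane, fell by 0.28 ± 0.06. Tested on every probe, this list's camera call ended (adjusted p = 0.0831). Without control replicate 4 and spermine oxidase replicate 1 together the calls ended for oxidative phosphorylation (adjusted p = 0.445, score difference 0.028), the tricarboxylic acid cycle and fatty acid oxidation (0.143, 0.046) and excitation-contraction (0.274, 0.051), while glycolysis stayed called with a score difference of 0.090. In each of these lists they were the lowest control and the highest spermine oxidase muscle, so the differences had to shrink. The fast fibre list was higher in 14 of 18 genes but was not called (adjusted p = 0.0508, and adjusted p = 0.456 with an estimated correlation), with Myh4, the fastest myosin heavy chain, at 0.34 ± 0.11 and Actn2, a Z-disc actinin, at -0.32 ± 0.11. Its adjusted p was 0.263 after quantile and 0.299 after loess normalization.

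Vessel, tendon and antioxidant genes were higher, each with scores that did not overlap between groups. The endothelium and vessel wall list was higher in 21 of 24 genes by 0.12 (adjusted p = 1.80e-05, and adjusted p = 0.456 with an estimated correlation). The water channel Aqp1 (0.65 ± 0.10, higher on all 3 of its probes), the angiopoietin receptor Tek (0.34 ± 0.06) and the endothelial adhesion molecule Pecam1 (0.21 ± 0.04) rose over the list alone. The tendon and cartilage list was higher in 11 of 14 genes by 0.25 (camera adjusted p = 0.000441, fry adjusted p = 0.0343, and camera adjusted p = 0.360 with an estimated correlation). Chad, Fmod, Kera, the proteoglycan keratocan (0.57 ± 0.11), Cilp2 (0.38 ± 0.08) and Mkx, a tendon transcription factor (0.15 ± 0.03), rose over the list alone. Kera, Cilp2 and Mkx lay close to the floor, at 8.77, 8.39 and 8.50 in control muscles, and the median gene of the list differed by 0.031. The list of NRF2 targets and antioxidant genes was higher in 16 of 26 genes by 0.094 (adjusted p = 0.00101, and adjusted p = 0.456 with an estimated correlation). The malic enzyme Me1 (0.92 ± 0.16), the glutathione S-transferase Gstm1 (0.51 ± 0.10), Gclm, a subunit of the enzyme that starts glutathione synthesis (0.30 ± 0.05), the glutathione peroxidase Gpx4 (0.23 ± 0.07), the superoxide dismutase Sod1 (0.22 ± 0.06) and Osgin1 (0.20 ± 0.05) rose over the list alone. The second probes of Gpx4 and Gstm1, near the floor, differed by -0.011 ± 0.03 and 0.06 ± 0.05.

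**Figure D2:**
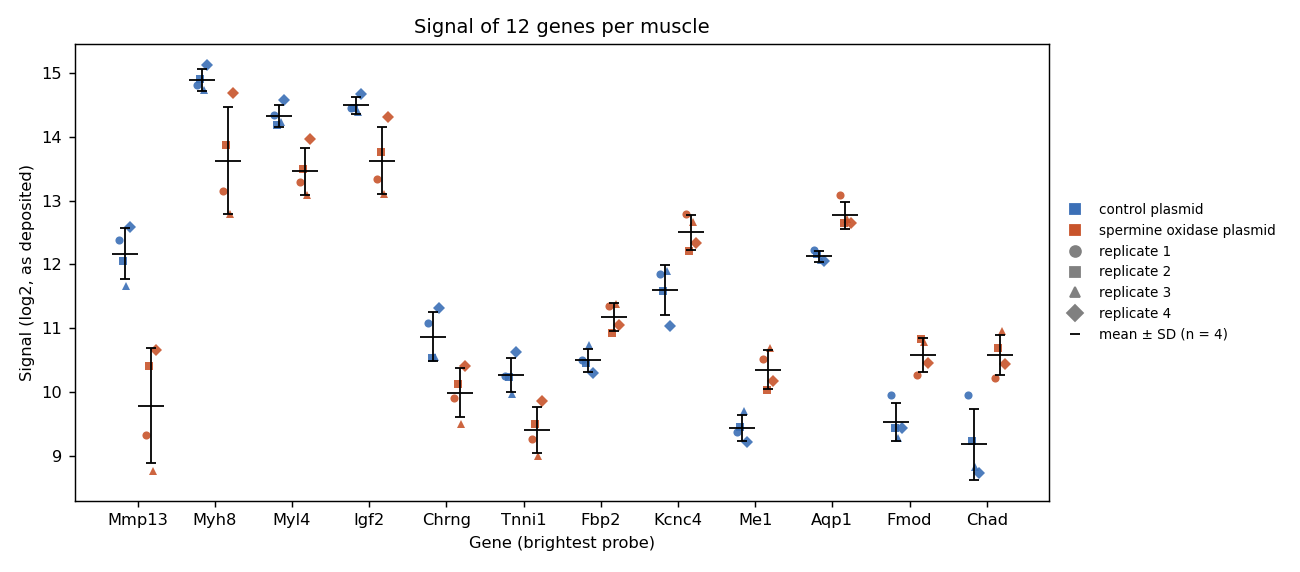
Signal of 12 genes (horizontal axis) on the deposited log2 scale (vertical axis) in each of the 8 muscles; colours give the plasmid, symbols the replicate number, and bars the mean ± SD of 4 muscles. Mmp13, Myh8, Myl4, Igf2, Chrng and Tnni1 are lower and Fbp2, Kcnc4, Me1, Aqp1, Fmod and Chad higher in all 4 spermine oxidase muscles than in any control muscle. The 12 genes are a selection of named genes, all without overlap. Other named genes, such as Sln, Ncam1, Tnnt1, Apoe, Ppp1r1a and Ces1d, overlapped between the groups and are not shown. None passed an adjusted p of 0.05 over all genes in the unpaired limma fit.

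Genes of protein synthesis, stress and growth moved by small amounts. Ribosomal protein genes were lower in 30 of 36 cases by -0.090 on average without overlap of the scores (adjusted p = 1.99e-05, and adjusted p = 0.456 with an estimated correlation), by -0.056 without control replicate 4, and by -0.033 without that muscle and spermine oxidase replicate 1, where the call stayed. Rps3 was the member with the smallest p (-0.19 ± 0.05) and did not pass over the list alone. The integrated stress and unfolded protein response list was lower in 19 of 25 genes by -0.067 (adjusted p = 0.0192, and adjusted p = 0.456 with an estimated correlation). Its members went both ways over the list alone. The asparagine synthetase Asns (-0.63 ± 0.16), the serine synthesis enzyme Psat1 (-0.44 ± 0.10), the amino acid transporter Slc7a5 (-0.43 ± 0.10) and the hormone gene Fgf21 (-0.32 ± 0.07) fell, while the transcription factor gene Atf4 (0.30 ± 0.08) and the endoplasmic reticulum genes Dnajb9 (0.22 ± 0.04) and Herpud1 (0.21 ± 0.05) rose. Muscle atrophy genes were higher in 17 of 28 by 0.081 (adjusted p = 0.0181, and adjusted p = 0.456 with an estimated correlation). The ubiquitin ligase gene Trim63 (0.50 ± 0.13) and Asb2 (0.63 ± 0.18) were among them and did not pass over the list alone. Cell cycle genes were lower in 18 of 22 by -0.11 (adjusted p = 0.00749, and adjusted p = 0.492 with an estimated correlation), with Cdk1, the mitotic kinase, at -0.38 ± 0.10 without passing. Without spermine oxidase replicate 1 the camera call ended for the stress list (adjusted p = 0.136, score difference -0.040), the atrophy list (0.0587) and the cell cycle list (0.0912, score difference -0.052). Without control replicate 3 these adjusted p-values were 0.101, 0.0603 and 0.200, the stress list also lost its call without spermine oxidase replicate 4 (0.0884) or the dimmest 60% of probes (0.0769), and the atrophy list without spermine oxidase replicate 2 (0.0629) or the dimmest 40% (0.0639) or 60% (0.146). Without control replicate 4 and spermine oxidase replicate 1 together the stress, atrophy and cell cycle calls ended as well (adjusted p = 0.200, 0.109 and 0.200).

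Markers of connective tissue and immune cells were lower on average, with wide spread between muscles. The macrophage and monocyte list was lower in 28 of 32 genes by -0.26 (adjusted p = 0.000441, and adjusted p = 0.456 with an estimated correlation). Ms4a7 (-0.71 ± 0.19), Lgmn, a lysosomal protease (-0.62 ± 0.21), and the complement gene C1qa (-0.43 ± 0.14) did not pass over the list alone. Cd163, a receptor of resident macrophages, rose by 0.22 ± 0.04 over the list alone at a signal near the floor. The extracellular matrix and fibroblast list was lower in 28 of 31 genes by -0.24 (adjusted p = 1.99e-05, and adjusted p = 0.456 with an estimated correlation), with Tgfb1, a growth factor, at -0.40 ± 0.11 and the collagen gene Col5a1 at -0.66 ± 0.28, neither passing. All 17 antigen presentation genes were lower, by -0.17 on average (adjusted p = 0.0224, and adjusted p = 0.667 with an estimated correlation), with Cd74, the class II invariant chain, at -0.25 ± 0.14. In comparisons that ignore the replicate numbers, these differences rested on few muscles. The macrophage score was 0.43 in control replicate 4 and -0.50 in spermine oxidase replicate 1, against -0.03 to 0.14 in the other 6. The difference was -0.16 without the former, -0.13 without the latter and -0.031 without both. The matrix score difference was -0.13 without control replicate 4 and -0.050 without both muscles. In replicates 1 to 4 the matrix score was -0.013, 0.025, 0.015 and 0.46 with the control plasmid and -0.36, -0.15, -0.20 and 0.22 with spermine oxidase. Compared by number, the matrix score was lower after spermine oxidase in each, and the macrophage and antigen presentation scores in each but number 2. Without both muscles the camera call ended for macrophages (adjusted p = 0.200), matrix (0.263) and antigen presentation (0.143). The call of antigen presentation ended without spermine oxidase replicate 1 (0.704, score difference -0.014, with the median turning to 0.0093), spermine oxidase replicate 4 (0.229, -0.11), control replicate 3 (0.377, -0.068) or control replicate 2 (0.0998), and its difference was -0.29 without spermine oxidase replicate 2 or 3 and -0.26 without control replicate 4. Array weights ended it too (0.0517).

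**Figure D3:**
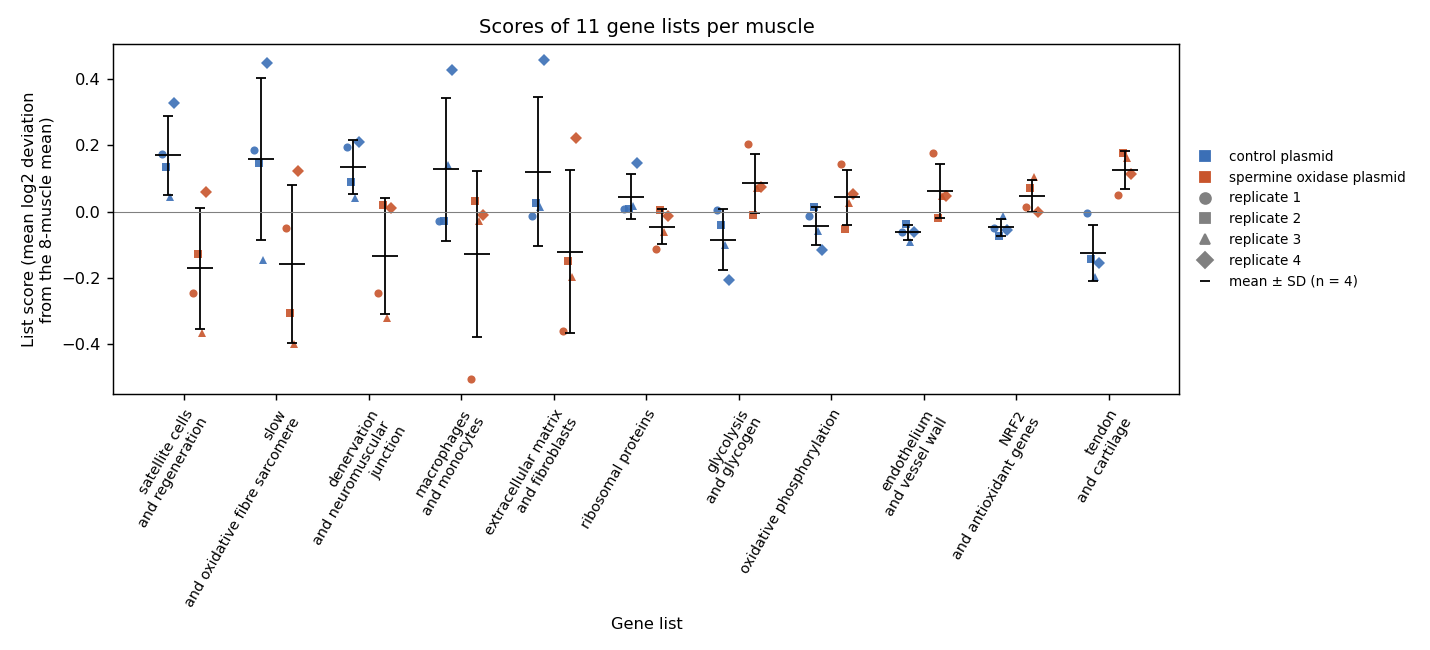
Scores of 11 gene lists (horizontal axis), each the mean log2 deviation of the list's genes from their means over the 8 muscles (vertical axis), in each muscle; colours give the plasmid, symbols the replicate number, and bars the mean ± SD of 4 muscles. Scores of the denervation, ribosomal, endothelium, NRF2 and tendon lists do not overlap between groups, while control replicate 4 (0.46) and spermine oxidase replicate 1 (-0.36) stand at the ends of the extracellular matrix list.

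The remaining lists were not called by camera at the preset correlation. Polyamine metabolism, the pathway of the overexpressed enzyme, showed no common direction (adjusted p = 0.934), with a median of -0.011 and a mean of 0.012. In it Amd2, an S-adenosylmethionine decarboxylase gene, rose by 0.78 ± 0.15 adjusted over the list alone, from 8.73 ± 0.20 to 9.51 ± 0.26 (SD, n = 4). Amd2 is nearly identical to Amd1, so its probe may read either gene. Sat1, the spermidine and spermine acetyltransferase, differed by -0.41 ± 0.18 and did not pass. Aldehyde detoxification genes were not called (adjusted p = 0.473), with Aldh6a1 at 0.58 ± 0.14. In the list of p53 targets (adjusted p = 0.796) Trp53inp1 fell by 0.15 ± 0.02 over the list alone, on 1 of its 2 probes, and Cdkn1a, the cell cycle inhibitor p21, differed by -0.60 ± 0.22. The adipocyte list (adjusted p = 0.115) held Plin4 (0.66 ± 0.19), Adipoq (0.54 ± 0.16) and Lep (0.17 ± 0.05), which rose over the list alone, and Thrsp, which fell by 0.32 ± 0.09. Camera called the adipocyte list higher without the dimmest 40% of probes (adjusted p = 0.0261) and with an intensity trend and robust prior (0.0398). Insulin and IGF signalling was not called (adjusted p = 0.815), with Grb10, an adaptor that restrains insulin signalling, at -0.79 ± 0.20. Erythrocyte genes were not called (adjusted p = 0.0672), with the globin gene Hba-a1, which shares its sequence with a near-identical copy, at 0.71 ± 0.21. No call was made for lymphocytes (adjusted p = 0.0672), the interferon response (0.0640), heat shock proteins (0.215), the proteasome (0.562), Schwann cells and nerve (0.686, with a median of -0.012 and a mean of 0.00066) or neutrophils and mast cells (0.924). Some of these lists were called with 1 muscle left out: fast fibre genes without control replicate 1 or 2 or spermine oxidase replicate 2, erythrocyte genes without control replicate 3 or spermine oxidase replicate 2, and lymphocyte and interferon genes, as lower, without control replicate 1 or 4 or spermine oxidase replicate 2 or 3. Unpaired settings on all 8 muscles added calls too: erythrocyte and lymphocyte genes without the dimmest 40% of probes (adjusted p = 0.0406 for both), fast fibre and interferon genes (0.0373 for both) and lymphocyte genes (0.0446) on every probe, fast fibre genes with the offset (0.0493), erythrocyte genes with array weights (0.0428), and erythrocyte, interferon (0.0253 for both) and lymphocyte genes (0.0398) with the intensity trend. Without spermine oxidase replicate 1 the interferon list turned to a median of 0.0048.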

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

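The rule for samples far from the rest of their group was set before the data were examined. It was applied to the Smox probes, the list scores and the genes named in the text, many of them chosen from these data. Of 246 groups of 4 values tested, 13 held a muscle whose gap to its nearest neighbour took up nearly the whole range of the group, and chance would give about 12, since it flags 1 in 20. That chance count is rough, because it takes no account of how the genes were chosen. Control replicate 4 held 4 of the 13. Its extracellular matrix score was 0.458, against -0.013 to 0.025 in the other control muscles, its ribosomal protein score was 0.148 against 0.0074 to 0.017, its Schwann cell score was 0.0526 against -0.020 to -0.015, and its Sod1 signal was 12.34 against 12.52 to 12.54. Spermine oxidase replicate 1 had a macrophage score of -0.504, against -0.029 to 0.031 in the other 3, and an Aqp1 signal of 13.09 against 12.65 to 12.71. Spermine oxidase replicate 2 had a p53 target score of 0.0566 against -0.0095 to -0.0065 and a Phka1 signal of 10.51 against 10.75 to 10.77. Spermine oxidase replicate 4 had a Sypl2 signal of 14.12 against 13.88 to 13.91, a Trim63 signal of 9.71 against 10.13 to 10.15 and a Col5a1 signal of 12.38 against 11.39 to 11.52. Spermine oxidase replicate 3 had a Thrsp signal of 8.87 against 9.04 to 9.07, and control replicate 1 a Gstm1 signal of 10.34 against 10.02 to 10.07.

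Outside the named genes, 1 probe without a gene name here was 1.19 higher after spermine oxidase, at 10.93 ± 0.70 in control muscles and 12.12 ± 0.09 in spermine oxidase muscles (SD, n = 4), with no overlap. It did not pass over all probes (limma adjusted p = 0.271). Of the 1719 unnamed probes, 178 had an unadjusted p under 0.05 and 0 passed when adjusted.

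Control replicate 4 and spermine oxidase replicate 1 also lay at opposite ends of the first principal component, at -16.4 and 18.8, against -7.20 to 6.68 in the other 6 muscles. That component held 47.5% of the variance. They had the lowest array weights, 0.76 and 0.59. If 1 such library made the shifts of the regeneration and glycolysis lists, leaving it out would end their calls, a test set before its result was seen. All 16 calls in the 8 leave-one-out fits of these lists stayed, and no single muscle changed either score difference by more than 1.31 times, which argues against that explanation. The kept calls are weak evidence on their own, since camera at the preset correlation called up to 16 lists in other splits of the muscles and neither list was called with an estimated correlation (adjusted p = 0.456). Both lists were also called without the 2 muscles together, although the glycolysis score difference shrank from 0.17 to 0.090 and that of the regeneration list from -0.34 to -0.26. The calls of the macrophage and extracellular matrix lists ended without both. In these lists the 2 muscles held the highest control and the lowest spermine oxidase score, so the differences had to shrink.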

How the results depend on the processing

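Smox stayed higher with an unadjusted limma p under 0.05 under every alternative tried, with a log2 difference of 0.74 to 3.44. No gene named in the text changed direction in any setting. With every probe on its own, however, a gene was still read by its brightest probe. That setting could therefore not show the opposite signs of dimmer probes, as seen for Cdsn, Gpx4, Dnajb9, Cdk1 and Trp53inp1. The count of 0 genes past the adjusted threshold became 8 with an intensity trend and robust prior and 567 at an unadjusted p under 0.01, and stayed 0 in the other unpaired settings on all muscles. It ran from 0 to 13 with 1 muscle left out, with 13 without spermine oxidase replicate 2. The count of 17 called lists became 0 with an estimated correlation, 1 with fry's test of direction and 8 without control replicate 4 and spermine oxidase replicate 1 together, and stayed at 13 to 21 in all other settings. The change to 0 lists came with the correlation setting alone. For the 17 called lists the estimated correlations ran from 0.023 (tendon and cartilage) to 0.86 (antigen presentation), all above the preset 0.01. The cause of the other changes was not tested, apart from the looser threshold of p and the fewer muscles. The 8 lists were denervation, endothelium, glycolysis, NRF2, ribosomal proteins, regeneration, slow fibre and tendon.

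With the replicate number as a replicate block, 266 genes passed, 137 higher and 129 lower, and 20 lists were called, the 17 and the erythrocyte (adjusted p = 0.0456), lymphocyte (0.0186) and interferon (0.0041) lists. Of the genes with at least 2-fold differences, this blocked limma fit passed Atp1b4 and Apoe (adjusted p = 0.0159 for both), Ppp1r1a (0.0271) and Dusp26 (0.0305). It also passed Mmp13 (0.0355), Ces1d (0.0391), Smox (0.0410) and Maged2 (0.0412), but not Myh8, Fmod or Chad. Deviations of same-numbered muscles from their group means correlated across genes at 0.60, -0.14, 0.67 and 0.60, over 0.1 in 3 of 4 pairs. The main fit had been set as unpaired because no label says that equal numbers pair the muscles. Since the muscles numbered 2 fell short of 0.1, it was kept so, but this check does not exclude pairing. The other 3 pairs hint at pairing, and 6 of 8 muscles correlated best with their own number. Whether equal numbers pair the muscles stays open, and the unpaired tests may miss differences that a pairing would show. Between same-numbered muscles the slow minus fast fibre score differed by -0.43 to -0.29 and the regeneration score by -0.42 to -0.26, lower in 4 of 4. An exact sign-flip test on 4 pairs gave 0.125 for each, the smallest p it can give. Normalizing again moved the median difference of all genes by less than 0.01.

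The lists whose tested direction turned were not called in the unpaired fit on all muscles, though the interferon response was called lower in other settings. Antigen presentation, called there, turned in its median only, to 0.0093 without spermine oxidase replicate 1. The insulin and IGF list had a median of 0.0038 with the mean of a gene's probes, 0.0044 with every probe on its own, and -0.018 to 0.0068 with 1 muscle left out. Neutrophils and mast cells had 0.00021 and -0.010 without the dimmest 40% and 60% of probes, and -0.013 to -0.00075 with 1 muscle left out, where camera's direction turned. Polyamine metabolism had -0.011 with the intensity trend and with fry, where the test's direction turned, and -0.019 to 0.0064 with 1 muscle left out. The interferon response ran from -0.23 to 0.0048 and the proteasome from -0.0030 to 0.023. The cause was not tested. Signal over background limits what dim genes can show, since the median probe lay at 8.33 and the floor near 8.10.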

Other observations

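Of the tests below, those on 1 added transcript, on the compressed scale, on invading cells, on the extent of injury and on splits for the adjusted count were chosen after the values they bear on had been seen; the others were set before their result was seen. The 35 splits of the 8 muscles into 4 and 4 were each fitted in the same way. For genes past an adjusted p of 0.05, the real count was 0, which all 35 splits must reach, so the comparison decides nothing; the highest other count was 1. For genes with an unadjusted p under 0.05, 1 of 35 splits, the real one, gave as many as 1833, and the highest other gave 1779. For lists called by camera, 1 of 35, again the real split, gave as many as 17, and the highest other gave 16. For these last counts the real split ranked first, but other splits came close to both, so chance is not excluded. The comparison also treats the 8 muscles as exchangeable, which would not hold if equal numbers paired them.

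The 5 Smox probes fell into 2 sets. The 3 probes near the floor in control muscles were highest in spermine oxidase replicate 2, at a mean of 13.15, while the 2 probes with high control signal were lowest there, at 11.39. If all 5 probes read 1 added transcript, the added linear signal of the sets would keep 1 ratio in the 4 treated muscles, but the ratio ran from 0.121 to 1.34, an 11.1-fold span, which argues against it. A compressed scale alone would keep the order of the muscles, but 3 of 6 pairs of treated muscles were in opposite order in the sets while over 0.25 log2 units apart in both. A hypothesis that stays open is that the high-control probes read a native Smox transcript, absent from the plasmid, that follows the mature state of each muscle: within groups, 11 of 12 pairs of muscles had the same order for these probes and for the glycolysis score, against 7 of 12 for the other probes and 6 expected by chance. Among control muscles both probe sets fell from replicate 1 to 4, as the glycolysis score did. The low-control probes read 8.91, 8.77, 8.73 and 8.49 there, and the high-control probes 10.99, 10.78, 10.76 and 10.03. The sets therefore differed in this respect only among treated muscles, and pairs that share muscles are not independent. The probes' places on the transcript were not analysed here, and a response of the native gene to the plasmid was not tested.

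The regeneration list was called lower and the glycolysis list higher by camera at the preset correlation, though neither with an estimated correlation (adjusted p = 0.456), and Myl4 was the only regeneration gene to pass over the list alone. Mmp13, a collagenase of tissue repair, had the largest fold difference of all genes when each was read by its brightest probe. Plasmid transfer can injure muscle, and 1 candidate explanation is that the control muscles held more regenerating tissue at 7 days. Fewer invading or connective tissue cells alone would shift slow and fast fibre genes alike. The slow minus fast fibre score differed by -0.36 with an exact permutation p = 0.0857 in a test that ignores the replicate numbers, which does not settle it, although the denervation score, of genes mostly expressed by fibres, was lower without overlap (exact p = 0.0286, adjusted 0.171), carried by a few genes, with a median gene at -0.077. In the unpaired comparison, differences in the extent of injury whatever the plasmid cannot be told apart from an effect of the plasmid either. The regeneration score overlapped between the groups, and its difference of -0.34 had an exact permutation p = 0.0571 (adjusted 0.171). Its SD was 0.12 among the 4 control muscles. Their range was 0.838 times the difference between the group means, a ratio that cannot decide the question because it gives no error rate. An effect of spermine oxidase on fibre maturation, or on injury and repair, stays open and was not tested.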
